A study of Homo sapiens with 12 samples.

How the data were processed

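Open chromatin had been profiled by DNase-seq, in which the enzyme DNase I cuts accessible DNA and the cut ends are sequenced, so that a high read count marks an open region. The 12 libraries came from 3 human breast cancer cell lines (MCF7, WS8 and TAMR), each exposed for 24 h to 4-hydroxytamoxifen (4-OHT) or to its vehicle, with 2 replicates per line and treatment. The labels' growth protocol gives 48 h of plating before treatment, and the series' design text gives another length of hormone-free culture. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

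The authors deposited a table of raw read counts for 486488 regions in the 12 libraries, in whole numbers and not normalised, with no region overlapping another. BWA, DESeq and the build hg19 (GRCh37) are named in the submitters' processing notes, without versions. The read filters, the counting tool and the peak caller are not given in the sources used here. The table's title says that transcription start sites were left out, which could not be tested without an annotation of that build. Every region of the table was covered by at least 1 of the 6 peak lists. A second kind of deposited file lists regions that differed between TAMR and WS8 under vehicle. Each entry carries a log2 fold change from the authors' DESeq run between these groups, per the file names. That it is TAMR over WS8 was read from the counts and the values. Each entry also carries a deposited p-value, all under 0.01, and whether that value is adjusted is not given in the sources used here. The third kind is 1 peak list per line and treatment, in which the authors gave each peak a score above 0.02. The scale of that score, and whether the replicates were pooled before peaks were called, are not given in the sources used here. The score was used only to rank peaks within a list.

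Counts were tested with edgeR 4.0.16 in R 4.3.3. Regions were kept by filterByExpr with a minimum count of 10, which left 354193 regions. Libraries were scaled by TMM, and the quasi-likelihood test was fitted to all 12 libraries as 6 groups, which share 1 estimate of the spread. The Benjamini-Hochberg false discovery rate (FDR) was held at 0.05 within each of 10 comparisons. Levels are TMM-scaled CPM with the SD over 2 libraries unless another n is given. Log2 fold changes are edgeR's estimates at its default prior count, with their standard error (SE). Log2 CPM, from which the medians of sets of regions were taken, used a prior count of 2. Sets of regions were tested with fry in limma 3.58.1, with Benjamini-Hochberg adjustment over the 10 set tests. Such a test asks whether the regions of a set move, on balance, one way. Medians of the sets were also set beside 10000 random sets matched on mean level (20 classes) and width (5 classes). With 2 libraries per group an exact permutation test of 1 pair of groups cannot go below a two-sided p of 0.333, so none was run. Overlaps of peaks were counted with bedtools 2.31.1 at a minimum of 1 bp, and intervals of shares are 95% Wilson intervals. Intervals cover counting error only, since the reads carry no molecular identifiers in the sources used here.

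On simulated counts with 100 changed regions per fold size among 323921 regions, at mean counts of at least 20, the TAMR against WS8 test recovered 6% of 2-fold and 69% of 4-fold changes with 0 false calls. The test of 4-OHT averaged over the lines recovered 61% and 99%, with 18 calls outside the regions changed for it. These 18 are not a count of false calls. Regions changed in vehicle-treated TAMR alone also shift that average, and they were not set apart. In the simulation all other regions were alike between the lines, and libraries of the same replicate number shared nothing. For TAMR against WS8, an FDR of 0.05 then needs a smaller p than in the data, where 55052 regions were called under vehicle. The recovered shares and the 0 false calls of that test therefore do not carry over to the data.

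The comparisons, the test, the alternatives and the rule for named regions were fixed before the data were examined. Named regions had an FDR under 0.05 and no overlap between the libraries compared, or the same direction in all 3 lines for the average. Of these, the 10 with the smallest p in each direction were taken for TAMR against WS8 under vehicle, and 5 in each direction elsewhere. Regions named outside this rule are said to be so. The alternatives were DESeq2's size factors, total counts, no filter, DESeq2 1.42.0, a block for the replicate number, leaving out each library, fitting only the libraries compared, a minimum of 2-fold, and a local offset. The local offset subtracts, per library, the running median over 5 Mb windows, so that only differences beyond the level of the surrounding chromosome are tested.

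Positions are on hg19, counted from 1. The gene table at hand was of another assembly, so no region was assigned to a gene. Tests of gene loci, gene lists and motifs and a correction for GC content had been planned, and they were not run for want of a genome of the build. For the chromosome-scale views, median log2 fold changes were taken over regions in bins of 5 Mb with at least 50 tested regions, and CPM was summed in bins of 500 kb on chromosome 18.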

Results

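DNase-seq measured chromatin accessibility in 3 related breast cancer lines. MCF7 is an estrogen receptor-positive breast cancer line, WS8 is an MCF7 derivative sensitive to 4-OHT, and TAMR is a derivative resistant to tamoxifen. 4-OHT is the active metabolite of tamoxifen and binds the estrogen receptor. Each line was treated with vehicle or 4-OHT for 24 h, in 2 libraries each, which gave 6 groups and 12 libraries. The series concerns the transcription factors GRHL2 and FOXA1 in endocrine therapy resistance, and the comparison of TAMR with WS8 asks which regions differ between resistant and sensitive cells.

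Total counts ran from 14228169 in TAMR vehicle replicate 2 to 18971191 in MCF7 4-OHT replicate 1, and the median region held 10 or 11 counts per library. The lines separated on the first 2 principal components of the 20000 regions used, with 57% and 22.9% of the variance. The second also parted the replicate numbers in MCF7 and TAMR. With 4-OHT and vehicle, MCF7 stood at 145 and 76.3 in replicate 1 and at 8.55 and 1.53 in replicate 2. TAMR stood at 46.8 and 68.5 in replicate 1 and at -5.76 and -9.82 in replicate 2. Replicates correlated across regions with r between 0.923 and 0.941 on log2 CPM, except for MCF7 under 4-OHT with 0.845. In that group replicate 1 stood apart, with 23.9% of its counts in the top 1% of regions against 19.9% in replicate 2. The highly counted regions at 1:121483762-121485575, 6:58773466-58780246 and 19:27731734-27740382 were lower in replicate 1 than in replicate 2 in both treatments of MCF7 and TAMR. At the first, vehicle-treated TAMR held 15325 and 64129 counts, while vehicle-treated WS8 held 48452 and 43165. No replicate pair had identical values, with 6.77% to 9.44% of regions at equal counts.

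TAMR and WS8 under vehicle differed at regions on every chromosome. Among those higher in TAMR, the region at 16:34441353-34443380 held 81.2 ± 0.66 CPM in TAMR against 7.75 ± 1.28 in WS8 (SD, n = 2 each, log2 fold change 3.39, SE 0.227, edgeR FDR 5.25e-07). The region at 10:97878308-97879211 held 22.5 ± 0.0642 CPM in TAMR against 2.38 ± 0.0486 in WS8, with 13.9 in vehicle-treated MCF7. At 17:1227160-1228035 TAMR held 20.3 ± 0.798 CPM and WS8 2.23 ± 0.36, with 2.23 in vehicle-treated MCF7. The strongest call, 18:44047462-44051954, reached 118 ± 13.4 CPM in TAMR against 15.7 ± 0.629 in WS8 (log2 fold change 2.92, SE 0.187, FDR 4.33e-07). Of the 10 regions named as higher in TAMR, 7 lay on chromosome 18, among them 18:43339082-43341148 (39.0 against 5.32 CPM) and 18:71607493-71611176 (48.0 against 6.57 CPM). With the local offset the log2 fold change was 1.18 at 18:44047462-44051954, 0.93 at 18:43339082-43341148 and 1.53 at 18:71607493-71611176. At 16:34441353-34443380 it was 3.52.

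Regions lower in TAMR, some nearly without counts, were found on several chromosomes. At 7:64712143-64713113 the 2 vehicle-treated TAMR libraries together held 3 counts and those of WS8 held 323, a level in TAMR of 0.926% of that in WS8 (95% exact counting interval 0.19% to 2.73%). At 1:29101498-29102463 TAMR held 2.27 ± 0.587 CPM against 36.5 ± 2.44 in WS8 (log2 fold change -3.99, SE 0.256, edgeR FDR 4.33e-07). The region at 11:61879806-61880273 held 0.976 ± 0.0309 CPM in TAMR against 16.6 ± 1.53 in WS8, and 8:144974032-144974312 held 1.08 ± 0.415 against 18.2 ± 2.26. Vehicle-treated MCF7 held 15.9 and 10.3 CPM at these regions. Chromosome 20 gave 4 of the 10 regions named as lower. Of these, 20:50232641-50232958 held 2.96 ± 0.143 CPM against 32.1 ± 1.49, and 20:50060811-50064879 held 41.0 ± 0.607 against 222 ± 25, with 53.1 CPM in MCF7. The local offset moved the log2 fold change from -3.44 to -2.01 at the former and from -2.44 to -1.04 at the latter.

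In all, edgeR called 55052 of 354193 regions between TAMR and WS8 under vehicle, 31746 higher in TAMR with a median log2 fold change of 1.58 and 23306 lower with a median of -1.47. A change of at least 4-fold was seen at 8134 of the higher and 4602 of the lower. Peaks in the deposited lists covered these calls unevenly: 63.7% of the higher regions overlapped a peak of vehicle-treated TAMR and none of vehicle-treated WS8, and 61.9% of the lower regions the reverse. The count depended on single libraries, falling to 16353 without WS8 vehicle replicate 1, 19474 without replicate 2, 21881 without TAMR vehicle replicate 1 and 26723 without replicate 2, and rising to 95097 without MCF7 4-OHT replicate 1 and 95112 without replicate 2. It was 28933 with DESeq2, 30244 with the local offset and 96129 when only the 4 libraries compared were fitted.

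The differences were laid out in blocks along the chromosomes. On chromosome 18 the median log2 fold change of TAMR over WS8 was 1.41 over 13444 regions, of which 6225 were called higher and 354 lower. That chromosome took 3.84% ± 0.0378 of all counts in vehicle-treated TAMR, 1.57% ± 0.00287 in WS8 and 1.48% ± 0.0715 in MCF7 (SD, n = 2 each). Chromosome 22 was also higher in TAMR, with a median of 0.64, and chromosome 20 was lower, with a median of -0.64 and 4044 of 14959 regions called lower. Chromosome 18 held 19.6% of all higher calls and chromosome 20 held 17.4% of all lower calls. Of 595 bins of 5 Mb, 85 had a median above 0.5 and 85 a median below -0.5. The lowest was on chromosome 1 at 115000001-120000000, with a median of -1.79, and the highest on chromosome 18 at 40000001-45000000, with 2.32. With the local offset, 498 regions of chromosome 18 were called higher and 731 lower.

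**Figure D1:**
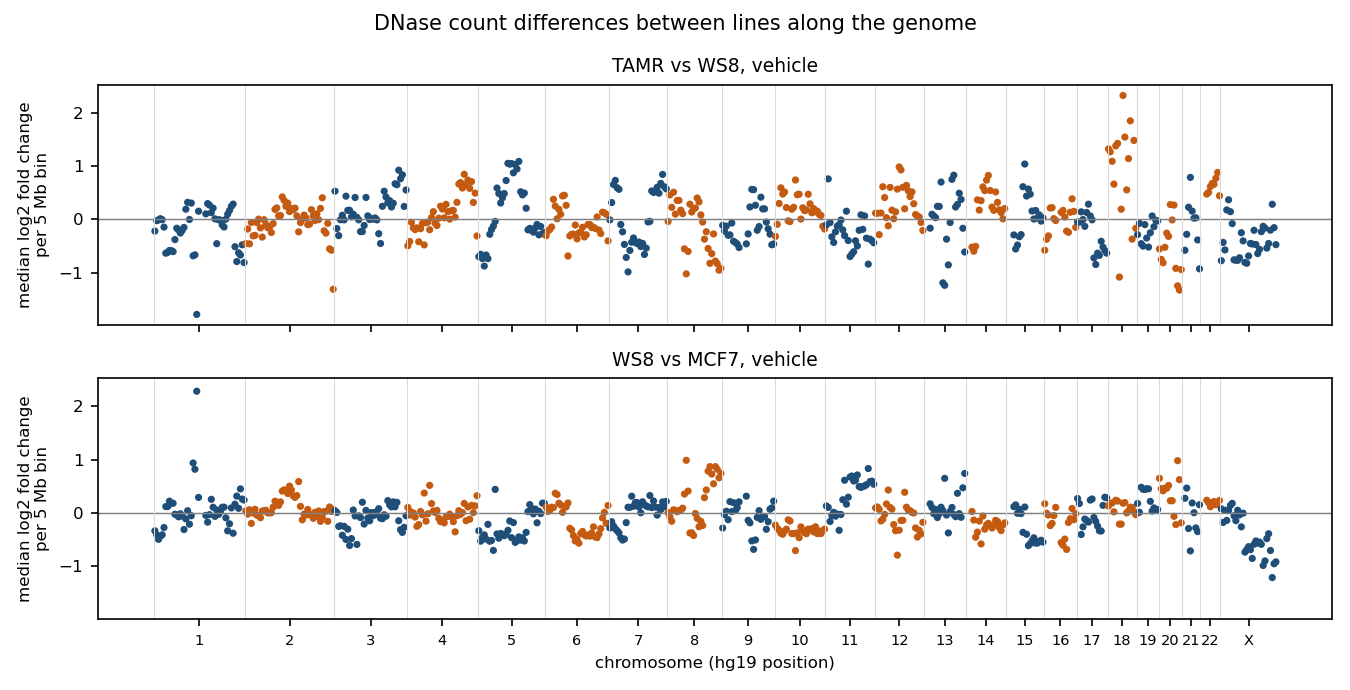
Each point is the median log2 fold change of the tested regions in a bin of 5 Mb, placed by hg19 position, for TAMR over WS8 (top) and WS8 over MCF7 (bottom), vehicle libraries. Chromosome 18 lies above 0 over most of its length in the upper panel, and the bin at 115000001-120000000 of chromosome 1 stands at -1.79 in the upper and 2.28 in the lower panel.

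Within chromosome 18 the highest and the lowest levels lay a few Mb apart. In the bin at 43000001-43500000, TAMR held 2591 ± 25.2 CPM and WS8 441 ± 4.56 (SD, n = 4 libraries each, both treatments), a ratio of 5.87. In the next bins the ratio was 5.50 and 5.14. In the bin at 52000001-52500000, TAMR held 0.669 ± 0.272 CPM and WS8 21.6 ± 2.08, a ratio of 0.0309. The ratio was above 4 in 5 of 149 bins of 500 kb and under 0.25 in 5 others, while that of WS8 to MCF7 stayed between 0.65 and 1.79.

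**Figure D2:**
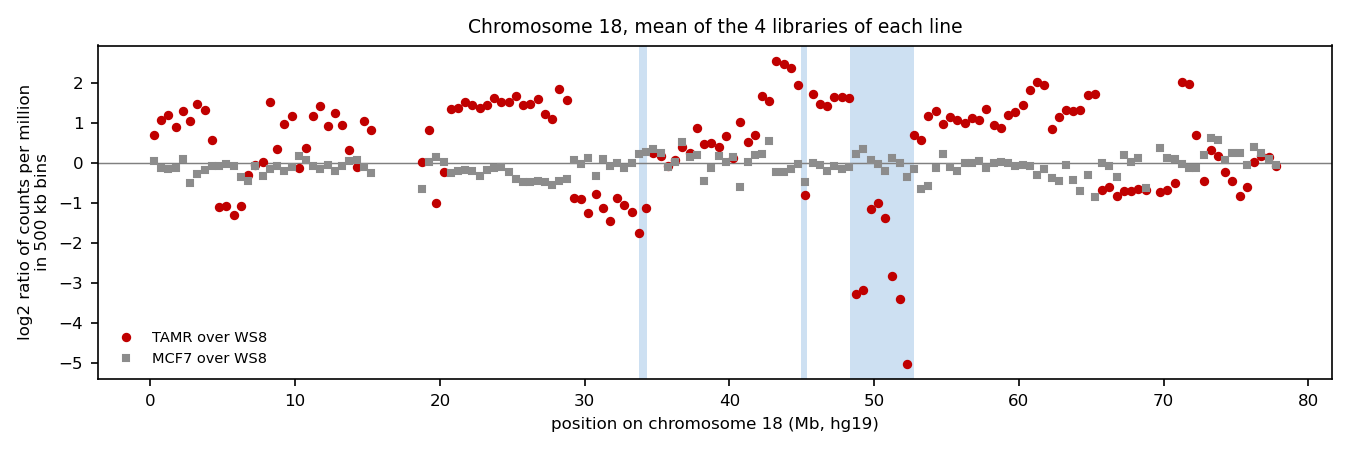
Log2 ratio of summed CPM in bins of 500 kb along chromosome 18 (hg19, Mb), mean of 4 libraries per line, for TAMR over WS8 (red circles) and MCF7 over WS8 (grey squares), with blue bands spanning the 3 stretches that hold 56 regions nearly without counts in TAMR. TAMR reached a ratio of 5.87 at 43000001-43500000 and fell to 0.0309 at 52000001-52500000.

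A search made after the data had been seen found 57 regions with at most 3 counts over the 4 TAMR libraries together and at least 10 counts in each of the 8 MCF7 and WS8 libraries. They were taken from 164893 regions with that minimum in MCF7 and WS8. The same search for regions missing from WS8 gave 0 of 153062, and for MCF7 0 of 158345. Of the 57 regions, 56 lay in 3 stretches of chromosome 18. At 33759995-34337420, all regions together held 41.5 ± 6.45 counts per library in TAMR, 844 ± 66.4 in WS8 and 1185 ± 158 in MCF7 (SD, n = 4 each). At 44948965-45342580 they held 66.5 ± 15.2, 856 ± 111 and 1263 ± 141 counts, and at 48311121-52763834 they held 345 ± 42.5, 2689 ± 123 and 3217 ± 443. In that last stretch 114 of 180 regions held at most 3 counts over the TAMR libraries, and the bins from 49500001 to 51000000 had ratios of TAMR to WS8 of 0.451, 0.501 and 0.386. The remaining region, 7:64720780-64720978, lay near the region of chromosome 7 named above.

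The comparison of TAMR with WS8 under 4-OHT asks whether the lines also differ in the presence of the drug. Its levels come from other libraries, while the fit, its filter and its estimate of the spread are shared. The regions at 16:34441353-34443380 (82.3 ± 6.89 against 7.26 ± 0.111 CPM), 15:79449693-79450656 (34.4 against 4.41 CPM) and 18:44047462-44051954 (114 ± 7.66 against 13.5 ± 0.846 CPM) were higher in TAMR. At the last of these the log2 fold change was 3.07, and 1.32 with the local offset. The regions at 1:29101498-29102463 (2.27 ± 0.0256 against 36.1 ± 0.638 CPM) and 11:61879806-61880273 (0.925 ± 0.194 against 16.0 ± 1.16 CPM) were lower. The edgeR test called 29631 regions higher and 23001 lower, of which 19818 and 13411 were also called in that direction under vehicle, where 2656 and 1513 would be shared by independent lists. Opposite calls were made at 4 regions. Across regions, which are not independent replicates, the fold changes correlated with r = 0.743. The total of 52632 moved to 14654 and 19111 without WS8 4-OHT replicates 1 and 2, to 20945 and 21365 without those of TAMR, and to 92118 and 92269 without those of MCF7. It was 27428 with DESeq2, 27479 with the local offset and 95613 with only the libraries compared.

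The authors' deposited table of higher regions held 9232 entries and that of lower regions 4556. Of these, 9226 and 4554 were called here in the same direction, and 0 were called in the opposite one. The direction of each list had been read from the counts, and the lists compare the same groups, so this is no independent check. In the authors' deposited table of higher regions 2205 entries (23.9%) lay on chromosome 18, and in that of lower regions 1448 (31.8%) lay on chromosome 20. With the local offset 6826 of the higher (73.9%) and 2364 of the lower entries (51.9%) of the authors' deposited tables were called.

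TAMR and MCF7 under vehicle were compared to see how the resistant line differs from the line it derives from. The region at 13:107222630-107223228 held 18.9 CPM in TAMR and 0.992 in MCF7 (log2 fold change 4.23, SE 0.28, edgeR FDR 3.23e-07), with 3.39 in WS8. The regions at 20:52374114-52374416 (14.9 against 126 CPM, log2 fold change -3.08), 17:64927030-64927494 (5.39 against 55 CPM) and 20:46056924-46057275 (12.3 against 75.9 CPM) were lower in TAMR. Chromosomes 18 and 22 were higher in TAMR, with median log2 fold changes of 1.63 and 0.83, and chromosome X and 21 were lower, with -0.99 and -0.50. The edgeR test called 40017 regions higher and 30392 lower. The total of 70409 moved to 29442 and 34911 without MCF7 vehicle replicates 1 and 2, to 30361 and 36891 without those of TAMR, and to 108833 and 108776 without MCF7 4-OHT replicates 1 and 2. It was 36371 with DESeq2 and 46853 with the local offset.

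WS8 and MCF7 were compared under vehicle to see how far the sensitive derivative has moved from MCF7, and edgeR called fewer regions than between TAMR and either line. All 5 regions named as higher in WS8 lay on chromosome 1 between 115676566 and 116707769. At 1:116255552-116256922 WS8 held 139 CPM and MCF7 24.3 (log2 fold change 2.52, SE 0.171, edgeR FDR 1.74e-06), and TAMR held 31.6. The regions at X:130926311-130927772 (2.53 against 34.3 CPM, log2 fold change -3.76), 19:37742158-37743140 (3.46 against 30.9 CPM) and 19:21182452-21183221 (2.97 against 26.3 CPM) were lower in WS8. Chromosomes 11, 8 and 20 had medians of 0.47, 0.43 and 0.34, and chromosome X had -0.54. In all, 7055 regions were higher and 5698 lower. With the local offset the split turned to 3399 higher and 4318 lower, and the log2 fold change at 1:116255552-116256922 became 0.58 (edgeR FDR 0.0502). The total of 12753 moved to 2885 and 2694 without WS8 vehicle replicates 1 and 2, to 3325 and 3203 without those of MCF7, to 8074 and 8221 without WS8 4-OHT replicates 1 and 2, and to 41627 and 41846 without those of MCF7. It was 8240 with DESeq2, and 43702 with only the libraries compared.

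At the regions called between TAMR and WS8 under vehicle, MCF7 was placed using the 4-OHT libraries alone. Where TAMR was higher, the median log2 difference from WS8 was 1.19 for TAMR and -0.10 for MCF7, and MCF7 was nearer WS8 at 86.8% of regions. Where TAMR was lower, the medians were -1.08 and -0.23, and MCF7 was nearer WS8 at 63.5%. Without MCF7 4-OHT replicate 1 the medians for MCF7 were 0.07 and -0.37, and without replicate 2 they were -0.25 and -0.09.

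The peak lists held 231829 to 265611 peaks. Of the vehicle-treated TAMR peaks, 57.3% overlapped a WS8 peak under vehicle (95% Wilson interval 57.1% to 57.5%), 61.5% an MCF7 peak and 73.9% a peak of 4-OHT-treated TAMR. Of the vehicle-treated WS8 peaks, 67.0% overlapped an MCF7 peak and 69.8% a peak of 4-OHT-treated WS8. Chromosome 18 held 5.30% of the peaks in vehicle-treated TAMR and 1.43% in WS8. No test was possible with 1 list per condition.

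4-OHT opened a small set of regions in MCF7. At 17:63239755-63240341 MCF7 rose from 6.04 ± 0.241 to 38.2 ± 8.17 CPM (SD, n = 2 each; log2 fold change 2.66, SE 0.21, edgeR FDR 6.88e-05), and at 1:203057895-203059363 from 14.9 to 53.0 CPM (log2 fold change 1.83). The regions at 13:101728819-101729061 (0.575 to 11.2 CPM), 10:129127235-129127970 (2.18 to 11.2 CPM) and 3:139032762-139033118 (1.45 to 7.46 CPM) rose as well. The edgeR test called 89 regions higher and 0 lower, with 19765 regions at an unadjusted p under 0.05, and DESeq2 called 182 higher and 0 lower. The count depended on single libraries: 339 without 4-OHT replicate 1, 40314 without replicate 2 (21108 higher and 19206 lower), 3 without vehicle replicate 1 and 7 without replicate 2, while leaving out TAMR replicates 1 and 2 gave 51 and 54 for 4-OHT and 54 and 55 for vehicle, and those of WS8 44 and 43 for 4-OHT and 49 and 50 for vehicle. A fit of the 4 MCF7 libraries alone called 0 regions, with 4614 at an unadjusted p under 0.05.

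In WS8, 4-OHT opened an overlapping set. The region at 17:63239755-63240341 rose from 4.98 ± 0.576 to 31.8 ± 3.21 CPM (log2 fold change 2.67, SE 0.214, edgeR FDR 8.22e-05), 20:47188624-47189167 from 11.6 ± 0.637 to 54.1 ± 2.34 CPM, and 22:43786975-43787926 from 3.25 ± 0.299 to 17.3 ± 1.65 CPM. The regions at 7:47581538-47582201 (2.76 to 12.7 CPM) and 1:65509864-65510625 (2.93 to 11.7 CPM) also rose. The edgeR test called 21 regions higher and 2 lower, and 16 of the higher were also called in MCF7, where 0.00528 would be shared by independent lists. The 2 lower regions lay within 2 kb of each other. At 16:33989596-33989719 counts fell from 118 to 2 over 2 libraries each, to 1.83% of the vehicle level (95% exact counting interval 0.219% to 6.76%), and at 16:33991300-33991425 the level fell from 3.99 ± 0.313 to 0.21 ± 0.0943 CPM. The total of 23 moved to 1 without either WS8 vehicle replicate 1 or 2, to 3 without either 4-OHT replicate, to 13 without any of the 4 TAMR libraries (vehicle 1 and 2, 4-OHT 1 and 2), and to 259 and 264 without MCF7 4-OHT replicates 1 and 2. It was 75 with DESeq2 and 733 when only the 4 WS8 libraries were fitted.

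In TAMR, edgeR called 0 regions between 4-OHT and vehicle, with 9766 at an unadjusted p under 0.05, and DESeq2 called 1. The regions that 4-OHT opened in the other lines stayed near their vehicle level. At 17:63239755-63240341 TAMR held 20.8 ± 0.598 CPM with vehicle and 22 ± 0.956 with 4-OHT, and at 1:203057895-203059363 it held 43.6 ± 1.76 and 41.8 ± 3.00. The region at 13:101728819-101729061 held 0.713 ± 0.503 and 5.64 ± 2.72 CPM (log2 fold change 3.02), without passing the threshold in TAMR alone. The count was 26 without MCF7 4-OHT replicate 1 or without replicate 2, 4 without MCF7 vehicle replicate 1 or without replicate 2, and 2 without TAMR 4-OHT replicate 2. It was 6 when only the 4 TAMR libraries were fitted.

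Averaged over the 3 lines, 4-OHT opened 108 regions and closed 0 by the edgeR test, with 13551 regions at an unadjusted p under 0.05, and DESeq2 called 193 higher and 1 lower. The region at 13:101728819-101729061 had an average log2 fold change of 3.35 (SE 0.274, edgeR FDR 6.02e-05), and 7:47581538-47582201 one of 1.43 and 20:36773092-36773801 one of 1.33. A call on the average does not show a response in each line. In TAMR alone these regions had log2 fold changes of 3.02, 0.07 and 0.09, so the averages at 7:47581538-47582201 and 20:36773092-36773801 rest on MCF7 and WS8. The count was 545 without MCF7 4-OHT replicate 1, 1247 without replicate 2 (774 higher and 473 lower), 52 and 49 without MCF7 vehicle replicates 1 and 2, 39 and 49 without TAMR 4-OHT replicates 1 and 2, and 39 and 40 without those of vehicle. It was 30 and 43 without WS8 4-OHT replicates 1 and 2, and 11 and 33 without those of vehicle.

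The response to 4-OHT itself was then compared between lines. It was weaker in TAMR than in WS8 at 17:63239755-63240341 (difference of log2 fold changes -2.60, SE 0.287, edgeR FDR 0.0135), 22:43786975-43787926 (-2.58, SE 0.309, FDR 0.0227) and 20:47188624-47189167 (-2.17, SE 0.28, FDR 0.042). It was weaker in TAMR than in MCF7 at 17:63239755-63240341 alone (-2.58, SE 0.284, FDR 0.0126). In vehicle-treated TAMR these regions stood at 20.8 ± 0.598, 21.0 ± 3.05 and 30.8 ± 1.34 CPM, against 4.98, 3.25 and 11.6 CPM in vehicle-treated WS8. The 3 calls against WS8 became 0 without any 1 of the WS8 or TAMR libraries (vehicle 1 and 2, 4-OHT 1 and 2), 63 and 64 without MCF7 4-OHT replicates 1 and 2, and 75 with only the 8 libraries compared. The call against MCF7 became 0 without any 1 of the TAMR libraries, MCF7 vehicle replicate 1 or 2, or WS8 4-OHT replicate 1 or 2, 49 and 13728 without MCF7 4-OHT replicates 1 and 2, and 14 with DESeq2.

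**Figure D3:**
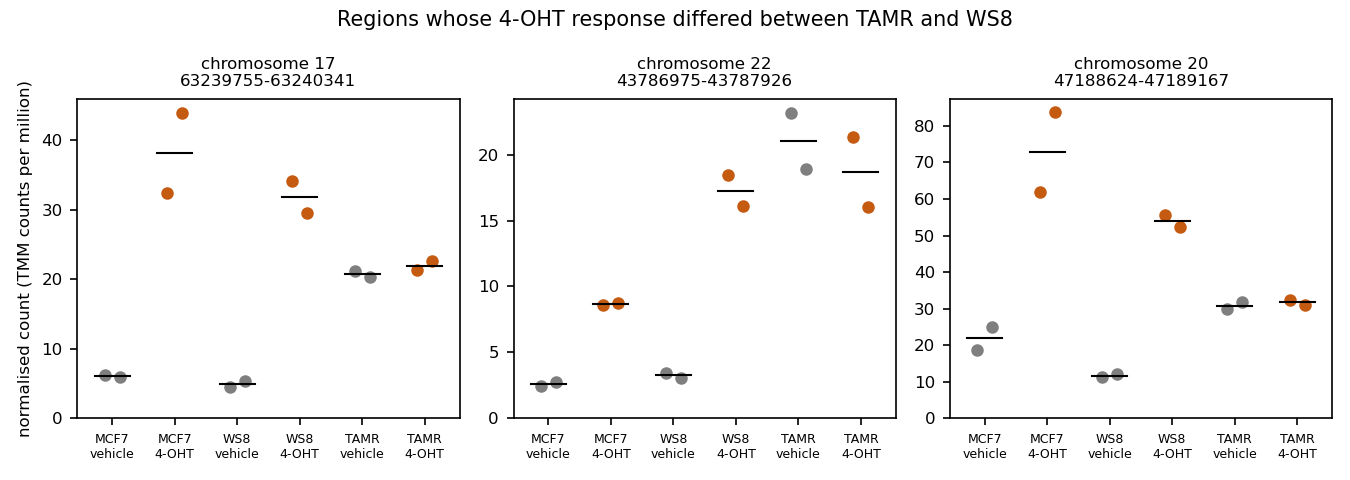
Normalised count (TMM-scaled CPM, linear axis from 0) of each library (points) and the mean of 2 libraries (black lines) at 3 regions, by line, with vehicle in grey and 4-OHT in orange. At 17:63239755-63240341 vehicle-treated TAMR stood at 20.8 CPM and WS8 at 4.98, and with 4-OHT they reached 22 and 31.8.

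A comparison chosen after the data had been seen followed the 89 regions called in MCF7 through the WS8 and TAMR libraries. Those libraries did not set the fold change in MCF7, but they shared the fit, its filter and its estimate of the spread. The selection was therefore not independent of them, and a fit of the 4 MCF7 libraries alone called 0 regions. In WS8 all 89 had a fold change above 0 with 4-OHT, with a median log2 of 1.23 (limma fry adjusted p = 1.69e-06). In TAMR the median was 0.04, with 52 of 89 above 0 (fry adjusted p = 0.48). The difference in response between TAMR and WS8 had a median of -1.13 and was above 0 at 4 of 89 regions (fry adjusted p = 8.59e-06). Under vehicle, TAMR exceeded WS8 at 76 of the 89 regions, with a median log2 difference of 1.23 (fry adjusted p = 2.58e-06), while the highest median of 10000 matched random sets was 0.40. The response in WS8 and the difference under vehicle share the vehicle-treated WS8 libraries. Vehicle-treated TAMR and 4-OHT-treated WS8 differed by a median of -0.09, with quartiles of -0.54 and 0.41 (fry adjusted p = 0.297), and of 0.05 with the local offset. Of the 89 regions, 60 were called higher in TAMR than in WS8 under vehicle and 3 lower, where 7.98 higher would be shared by independent lists. Peaks of vehicle-treated TAMR covered 69 of the 89, those of vehicle-treated MCF7 46 and those of vehicle-treated WS8 20. Without MCF7 4-OHT replicate 1 the selection gave 336 regions, with a median of 0.99 for the response in WS8, 0.03 for that in TAMR and 1.17 for TAMR over WS8 under vehicle.

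The 21 regions called higher in WS8 gave a like picture in the MCF7 and TAMR libraries. The median response was 1.55 in MCF7 (fry adjusted p = 1.69e-06) and 0.04 in TAMR (fry adjusted p = 0.728). Under vehicle, TAMR exceeded MCF7 at 20 of 21, with a median of 1.32 (fry adjusted p = 1.69e-06). The response differed between TAMR and MCF7 by a median of -1.51, and at 0 of 21 regions was it larger in TAMR (fry adjusted p = 3.23e-06). Vehicle-treated TAMR lay below 4-OHT-treated MCF7 by a median of -0.28 (fry adjusted p = 0.0127), and by -0.0076 with the local offset.

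**Figure D4:**
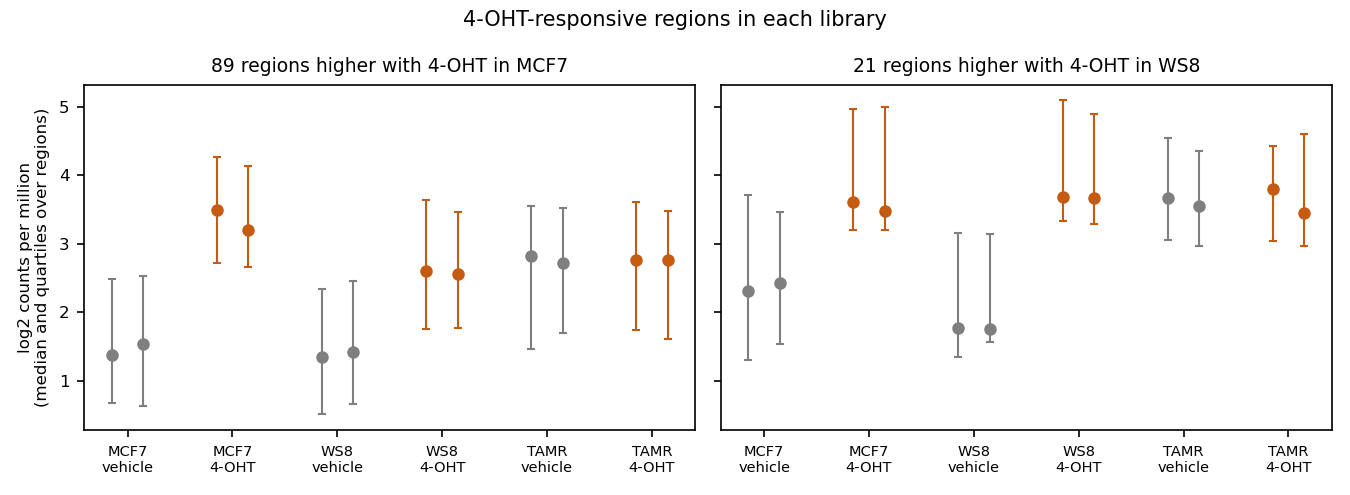
Median log2 CPM (points, 1 per library) and quartiles over regions (bars) at the 89 regions higher with 4-OHT in MCF7 (left) and the 21 higher in WS8 (right), with vehicle in grey and 4-OHT in orange. At the 89 regions the vehicle libraries stood at 1.37 and 1.54 in MCF7, 1.35 and 1.43 in WS8, and 2.83 and 2.73 in TAMR, and the 4-OHT libraries of TAMR both stood at 2.76.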

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

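The sets of regions followed here, and the test of whether vehicle-treated TAMR matched the level of 4-OHT-treated WS8, were chosen after the result was seen, as was the test of a ceiling over all regions higher in TAMR. The other tests in this part had their outcome written down before it was computed.

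The response to 4-OHT differed between lines at 3 single regions by a test of the difference itself. At 17:63239755-63240341 TAMR differed from WS8 by a log2 response of -2.60 and from MCF7 by -2.58, at 22:43786975-43787926 from WS8 by -2.58, and at 20:47188624-47189167 from WS8 by -2.17 (edgeR FDR 0.0135, 0.0126, 0.0227 and 0.042). Over the 89 regions called in MCF7 the median difference between TAMR and WS8 was -1.13, and over the 21 regions called higher in WS8 the median difference between TAMR and MCF7 was -1.51.

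Most of the 89 regions that 4-OHT opened in MCF7 were already more open in vehicle-treated TAMR, with 76 above WS8 under vehicle and a median log2 excess of 1.23. Peaks of vehicle-treated TAMR covered 69 of them, those of vehicle-treated MCF7 46 and those of vehicle-treated WS8 20. The peak lists are of the same conditions as the counts, so they are no independent support. Peak cover also did not follow the level alone, since the median log2 CPM was 1.37 and 1.54 in vehicle-treated MCF7 and 1.35 and 1.43 in WS8. The tables argue against local copy number, since the median was 1.29 after the local offset, against the replicate number, since the lower of the medians within a number was 1.16, and against a property of any region of such strength and width, since no matched random set exceeded 0.40. A hypothesis left open is that TAMR may hold, without fresh 4-OHT, the accessibility that the drug induces in sensitive cells. The median of vehicle-treated TAMR minus 4-OHT-treated WS8 was -0.0923. A value near 0 is not particular to these regions, since the medians of the matched random sets lay between -0.372 and 0.355. At the 21 regions called higher in WS8, vehicle-treated TAMR minus 4-OHT-treated MCF7 had a median of -0.28 (limma fry adjusted p = 0.0127), and of -0.0076 with the local offset. A ceiling on accessibility as the reason for the missing response in TAMR is argued against at 24 regions that were not higher by 0.5 in TAMR. Their median response was -0.00642 in TAMR and 0.66 in WS8. A ceiling is also argued against at 10 higher regions that WS8 took at least 0.5 further, with a median TAMR response of 0.0848. The median of 1.83 in WS8 at these 10 follows from how they were chosen and adds no support. At the other 55 regions higher in TAMR the level of WS8 cannot tell a ceiling from an absent response, since 4-OHT-treated WS8 stood less than 0.5 above vehicle-treated TAMR there. The median TAMR response over all 65 higher regions was 0.0433. Over all 89 regions 4-OHT-treated MCF7 had median log2 CPM of 3.49 and 3.21, against 2.83 and 2.73 in vehicle-treated TAMR. The 89 regions were chosen for their high level in these MCF7 libraries, and MCF7 was not set against TAMR at the 55 regions.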

How the results depend on the processing

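The local offset combined with the block, the local offset for the authors' lists and the position of MCF7, and all alternatives for the set medians were chosen after seeing the data, the others before. No named region changed direction over 1415 values for 71 pairs of named region and comparison, in which a region can recur. Of the values, 1338 kept their direction and their side of the threshold and 77 kept the direction only, and 53 pairs passed throughout. These regions had the smallest p in the same libraries, so a kept direction was likely from the start. In the order TAMR against WS8 with vehicle and with 4-OHT, TAMR against MCF7 and WS8 against MCF7, the local offset gave 30244, 27479, 46853 and 7717 calls, and DESeq2 28933, 27428, 36371 and 8240. Only the libraries compared gave 96129, 95613 and, for WS8 against MCF7, 43702. For 4-OHT in MCF7, WS8 and TAMR, DESeq2 gave 182, 75 and 1, and only the libraries compared 0, 733 and 6. The local offset gave 183 in MCF7 and 76 in WS8, and no filter gave 36 in WS8. The average gave 219 with the local offset, 194 with DESeq2 and 57 at 2-fold or more. The difference in response gave 75 for TAMR minus WS8 with only the libraries compared, and for TAMR minus MCF7 0 with these, 3 with the local offset and 14 with DESeq2.

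The replicate numbers did not pair the libraries by the rule set: deviations of same-numbered libraries correlated with r of 0.0143 to 0.337 over 15 pairs of groups, 7 of them above 0.1, and 1 of 9 pairs with WS8. All 6 pairs without WS8 were above it, at 0.194 to 0.337, so same-numbered libraries of MCF7 and TAMR deviated together. With the replicate block, WS8 against MCF7 gave 22653 calls, 4-OHT gave 264 in MCF7, 103 in WS8, 8 in TAMR and 240 on average, and TAMR minus MCF7 gave 10. With the local offset and the replicate block, 4-OHT gave 359, 168, 14 and 342, TAMR minus WS8 16 and TAMR minus MCF7 18.

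Leaving out 1 library in turn gave, in the same order, 16353 to 95112, 14654 to 92269, 29442 to 108833 and 2694 to 41846 calls, for 4-OHT 3 to 40314, 1 to 264, 0 to 26 and 11 to 1247, and for the differences in response 0 to 64 and 0 to 13728. A group left with 1 library was assumed to vary like the others. At the 89 regions the median of TAMR over WS8 was 1.29 with the local offset, 1.16 in replicate number 2 alone, and 1.16 to 1.24 without 1 library. Vehicle-treated TAMR minus 4-OHT-treated WS8 had there a median of 0.052 with the local offset, -0.066 with DESeq2's size factors and -0.151 in replicate number 1 alone, and at the 21 regions called in WS8 vehicle-treated TAMR minus 4-OHT-treated MCF7 had -0.0076 with the local offset and -0.327 in replicate number 2 alone. Of the authors' lower regions 2364 were called with the local offset. The cause of these shifts was not tested.

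Peak overlap changed with the criterion, in the order 50% reciprocal overlap, top-scoring part of each list, and equal numbers of top peaks: TAMR in WS8 with vehicle 45.0%, 72.0% and 73.7%, vehicle in 4-OHT for TAMR 66.4%, 89.4% and 89.2%, for WS8 62.1%, 85.6% and 85.4%, and for MCF7 66.6%, 87.6% and 87.0%, WS8 in MCF7 56.9%, 81.8% and 79.2%, and TAMR in MCF7 48.7%, 74.9% and 74.3%. The authors' regions have the table's own coordinates, so 50% overlap changes nothing there. Gene loci, gene lists, motifs and GC corrections were not run. For the average over lines, fitting only the libraries compared is the same fit.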

Other observations

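The tests of lost DNA, of closing of single regions and of the replicate number on chromosome 18 were chosen after the result was seen, as were the search for regions nearly without counts and the test of the MCF7 response at regions that separate TAMR from WS8. The copy number test and the count of other splits had their outcome written down before it was computed.

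Of the 89 regions that 4-OHT opened in MCF7, 2 had log2 fold changes above 1 in all 3 lines, and neither was called in WS8 or TAMR alone. Besides 13:101728819-101729061, with log2 fold changes of 4.27 in MCF7, 2.76 in WS8 and 3.02 in TAMR, the region at 12:22156922-22157178 had 5.69, 1.89 and 3.43. It was chosen after its values were seen, and its counts in 4-OHT-treated MCF7 were 413 and 68, so that 1 library set much of its fold change. By contrast, 17:55173971-55174572, also chosen after its values were seen, rose in MCF7 from 4.58 to 16.8 CPM and stood at 4.20 and 5.23 CPM in WS8 and 3.52 and 3.63 CPM in TAMR with vehicle and 4-OHT.

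Chromosome-wide shifts between TAMR and WS8 were led by chromosome 18, with a median log2 fold change of 1.41. A difference between replicate numbers is argued against, since the lower of the medians within a number was 1.18 on the log2 CPM scale. A difference in DNA copy number is a candidate explanation. The weakest 25% of regions moved by 1.29 times the median of the strongest 25% on chromosome 18, 1.58 times on chromosome 22 and 0.594 times, the lowest, on chromosome 20. This test cannot decide, because weak regions could enter the count table and pass the filter through the line where they are high. On chromosome 18 the weakest 25% had a median mean count of 5.5, under the filter's minimum of 10. Vehicle-treated TAMR had 12832 peaks there and vehicle-treated WS8 3326. A regulatory change over whole chromosomes was not tested, and no DNA measurement was used here.

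The 57 regions open in MCF7 and WS8 and nearly without counts in TAMR may mark DNA that TAMR lost on chromosome 18. Over all 219 other regions of the 3 stretches the median ratio of TAMR to the other lines was 0.0928 (quartiles 0.0155 and 0.357), and over the 168 that lay between selected regions at most 250 kb apart it was 0.0898, which argues against the closing of single regions alone. A loss of the whole of each stretch is not supported, since 39 of the 219 had a ratio above 0.5, and the bins of 500 kb from 49500001 to 51000000 had ratios of TAMR to WS8 of 0.451, 0.501 and 0.386. A closing of chromatin over the whole of each stretch was not tested.

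The number of regions called for 4-OHT averaged over the lines does not exclude chance as measured by other splits of the libraries. Of the 108 possible splits 24 were drawn, and 5 of these, the real one included, called at least as many as the real 108 regions, with 10915 as the highest of the others. Of the 4 splits that parted both MCF7 and TAMR by replicate number, 3 gave 6850 to 10915 regions and 1 gave 0, so a structure of the samples by number is possible. A split that kept the treatments apart in MCF7 and WS8 and parted TAMR by number gave 163. The 8 other splits that parted neither MCF7 nor TAMR by number gave at most 0, and with the replicate number as a block the real split gave 240.

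The reverse question, whether 4-OHT moved MCF7 towards TAMR at the regions that separate TAMR from WS8, stays open. The median MCF7 response was -0.06 at regions higher in TAMR (limma fry adjusted p = 0.956) and 0.06 at regions lower in TAMR (limma fry adjusted p = 0.956), and both signs differed between the replicate numbers. The regions went both ways, and so large a set cannot exclude a move at some of them.

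Between 8.71% and 10.1% of the peaks in each deposited list lay outside the regions of the count table. Their median score, as the authors gave it, was 0.0845 to 0.153, against 0.0271 to 0.0296 inside, and they made up 41.1% to 46.5% of the top 10% of each list by score. These peaks were not tested for differences, because the count table holds no counts for them.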
